A study of Saccharomyces cerevisiae with 18 samples.

How the data were processed

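SLAM-seq was used to follow newly made mRNA in Saccharomyces cerevisiae. In this method cells are fed 4-thiouracil (4tU), RNA is alkylated with iodoacetamide, and an incorporated 4tU is read as a T-to-C conversion in the sequencing reads. Per the labels' protocols, cultures grown in YPD at 30 °C received 1 mM 3-indoleacetic acid (IAA, an auxin) in DMSO or DMSO alone for 25 min, then 5 mM 4tU or DMSO for 4 min, and were stopped in cold methanol. Per the series design text, 4tU-labelled Schizosaccharomyces pombe cells were mixed with the S. cerevisiae cells at a mass ratio of 1 to 19, before RNA extraction, as a spike-in. Per the labels' protocols, experiments were done in biological triplicate.

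Per the series design text, the libraries were 3′ mRNA-seq libraries sequenced as paired-end 150 bp reads, and the reads were processed with fastp, bbduk and SLAM-DUNK. The version of fastp was 0.23.2, per the submitters' processing notes, which also name the genome builds R64 (S. cerevisiae) and ASM294v2 (S. pombe). The version of SLAM-DUNK was 0.4.3, per the file headers. The settings of the trimming, mapping and conversion calling, and whether sequence variants of the strains were masked, are not given in the sources used here. The kit and the use of unique molecular identifiers are likewise not given in the sources used here, so reads may include copies of 1 molecule and counting error is a lower bound on the error.

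The authors deposited 72 tables of read counts, 4 for each of the 18 libraries: 1 for each species with a conversion threshold of at least 1 T-to-C change per read, and 1 for each species with a threshold of at least 2. Each deposited table gives, per gene window, the count of all reads, the count of reads at or above the conversion threshold, the count of multimapped reads and the coverage on T positions. The S. cerevisiae tables hold 6465 windows, of which 6462 matched a gene of the R64 annotation by name and position. In 99.97% of them the window ran from the start of the gene to 250 bp downstream of its end. 1316 windows overlapped another window on the same strand. The S. pombe tables hold 6974 windows.

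Samples were grouped by the strain and treatment named in their labels, with 3 libraries in each of 6 groups. Reads with at least 2 T-to-C conversions, called labelled reads, were taken as the measure of new RNA, and all reads as the measure of total RNA. New RNA was tested over the 12 libraries given 4tU and total RNA over all 18 libraries, with a separate mean for each group and 1 shared estimate of the spread. Genes were kept with at least 10 reads of the tested kind in at least 3 libraries, which left 5195 genes for new RNA and 6100 for total RNA. Libraries were scaled to their summed S. pombe reads of the same kind, so that a fold change is a change per S. pombe read. Tests were edgeR's quasi-likelihood F test with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. The standard error of a log2 fold change was its size divided by the square root of F. Scaled counts per gene are counts divided by the library's S. pombe sum and multiplied by the mean of those sums.

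Ratios and shares per library were compared with exact permutation tests, two-sided. With 3 libraries against 3, the smallest p such a test allows is 0.1. The difference between the strains in the effect of IAA was tested on residuals of a model with additive strain and treatment terms. Strain labels of the residuals were permuted within each treatment (400 arrangements, smallest p 0.005). Because residuals of a fitted model were permuted, the p of that test is approximate and not exact.

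Gene lists were tested with camera of limma on log2 spike-scaled counts (prior count 2) with a preset correlation of 0.01 between genes, and again with an estimated correlation, also under relative scaling (TMM over S. cerevisiae genes) and with a threshold of 1 conversion. Camera asks whether the genes of a list changed more or less than all other genes, so a list can be lower in cells and still lie up relative to the other genes. Lists needed at least 5 tested members. Members were counted as risen or fallen at the threshold over all tested genes, and again adjusted over the list alone. The lists were the engineered loci, cytosolic ribosomal proteins, ribosome biogenesis, translation factors, glycolysis and fermentation, Hsf1 chaperone genes, Msn2/4 stress genes, Yap1 oxidative stress genes, drug and weak-acid efflux, amino-acid biosynthesis under Gcn4, the phosphate regulon, histones, G1/S genes, G2/M and M/G1 genes, nuclear genes of oxidative phosphorylation, mitochondrial ribosomal proteins, the proteasome, RNA polymerase II with TFIID, SAGA and Mediator, ergosterol, pyrimidine and purine synthesis, glucose-response regulators, mating genes, meiosis genes, genes within 30 kb of a chromosome end, and intron-containing genes outside the ribosomal protein list. Members of the pyrimidine list include uracil salvage, the route by which 4tU enters nucleotides. A pair of listed symbols with a comma in the name, ARG5,6 and ADE5,7, found no match. As a description of effect size, each list median was also placed among 10000 random lists of the same size matched on mean count in 20 bins.

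Named genes were chosen by a fixed rule. It takes the engineered loci, then the 8 largest rises and 8 largest falls per comparison among called genes with a mean count of at least 50 whose libraries all lay on 1 side of the other group's mean. It also takes the 2 members of each list with the smallest p at a mean count of at least 50. The sample groups, tests, gene lists, the rule for named genes and most alternatives were set before the data were examined. Alternatives and tests added later are named as such where their values are given.

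The scripts were tested on simulated counts drawn from the means, spread and depth of the real libraries, with 40 genes changed by each fold. The changed genes were drawn from those with a mean of at least 20 scaled reads in RDY73 with DMSO. The shares found therefore hold for better-covered genes and may be lower over all tested genes. For new RNA in RDY73 (4601 genes simulated), the test called 100% of genes lowered 4-fold, 55% of those lowered 2-fold, 20% of those lowered 1.5-fold, 27.5% of those raised 1.5-fold and 87.5% of those raised 2-fold, with 4 false calls among 4401 unchanged genes. For total RNA in RDY73 (5997 genes simulated) the shares were 100%, 95%, 62.5%, 70% and 95%, with 5 false calls among 5797 unchanged genes. Camera called a list lowered in the simulation and 0 of 20 unchanged lists, for both kinds of count. Genes were simulated independently of each other, so this cannot show how often camera with the preset correlation errs where genes vary together.

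Alternatives were a threshold of 1 conversion, other scalings with and without the spike-in, DESeq2 in place of edgeR, no filter on low counts, fits on the compared libraries alone, replicate letters as a block, subtraction of background conversions, removal of overlapping windows and the omission of each library in turn. Gene windows with mostly multimapped reads (23 among the genes tested for total RNA) were kept. Reads without a gene window were not analysed here. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.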

Results

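Newly made and total mRNA were measured in 2 budding yeast strains in which the BET-family proteins Bdf1 and Bdf2 carry an auxin-inducible degron. Bdf1 and Bdf2 bind acetylated histones through bromodomains and associate with the general transcription factor TFIID. Both strains express OsTIR1, the plant F-box protein that directs degron-tagged proteins to the proteasome when auxin (IAA) is added. In strain RDY73 both proteins are tagged and no other copy is given in the genotype. Strain RDY234 carries the same tagged genes and also an untagged BDF1 copy under its own promoter. Each strain had 3 groups of 3 biological replicates: a control without IAA or 4tU, a DMSO group given 4tU for 4 min, and an IAA group given 1 mM IAA for 25 min and then 4tU. The series concerns a workflow for following new mRNA after a protein is rapidly removed, and the comparisons below ask how new and total mRNA changed with IAA in each strain, whether the strains differed, and what 4tU itself changed.

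The 18 libraries held 4177363 to 8541751 S. cerevisiae reads and 387855 to 792178 S. pombe reads in gene windows. S. pombe made up 6.91% to 11.4% of the reads of a library. Labelled S. cerevisiae reads, those with at least 2 T-to-C conversions, numbered 103348 to 574103 in the 12 libraries given 4tU and 10590 to 30610 in the 6 libraries without it. Labelled S. pombe reads, which set the scale for new RNA, numbered 8710 to 17677. On simulated counts of this depth the test found 55% of better-covered genes lowered 2-fold in new RNA of RDY73, against 95% in total RNA.

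The engineered loci were examined first. BDF1 (YLR399C, R64 chromosome XII 919536 to 921596, minus strand) had 751 ± 25.2 scaled total reads in RDY73 with DMSO and 2458 ± 14.2 in RDY234 with DMSO (SD, n = 3), a log2 difference of −1.71 ± 0.12 (SE, adjusted p = 1.06e-14). TRP1 (YDR007W, chromosome IV 461842 to 462516), the marker given for the untagged BDF1 copy, had 14.1 ± 1.00 scaled reads in RDY73 and 332 ± 31.2 in RDY234. Both values went with the genotypes in the labels. BDF2 (YDL070W, chromosome IV 331024 to 332940, plus strand) had 1573 ± 99.9 and 2158 ± 122 scaled reads. HIS3, the marker given for OsTIR1 in both strains, had 1 to 14 reads per library in its reference window, and URA3, the marker of the BDF1 tag, had 8288 ± 688 scaled reads in RDY73 and 9495 ± 529 in RDY234 with DMSO. The reads come from the 3′ ends of transcripts and the degron acts on protein, so they check the strain labels and not the loss of Bdf1 or Bdf2. With IAA, BDF1 total RNA changed by −0.08 ± 0.12 in RDY73 (adjusted p = 0.573) and −0.07 ± 0.12 in RDY234 (adjusted p = 0.824) on the log2 scale. BDF2 total RNA changed by −0.20 ± 0.13 (adjusted p = 0.151) and −0.02 ± 0.13 (adjusted p = 0.952). Without the spike-in, with libraries scaled over the S. cerevisiae genes, the RDY73 values turned positive, at 1.06 for BDF1 and 0.94 for BDF2.

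Labelling was clear over background in both strains. In RDY73, 4.08% ± 0.313 of S. cerevisiae reads were labelled with DMSO and 4tU, against 0.202% ± 0.0171 without 4tU (SD, n = 3 each), a 20.3-fold difference. In RDY234 the shares were 7.29% ± 0.122 and 0.373% ± 0.0356, a 19.6-fold difference. The exact permutation p was 0.1 in each strain, the smallest that 3 libraries against 3 allow, and 0.005 over both strains, the smallest possible there. Counted as conversions per covered T, the values were 0.554% ± 0.0373 against 0.151% ± 0.00424 in RDY73 and 0.924% ± 0.0384 against 0.214% ± 0.00432 in RDY234.

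IAA lowered labelled mRNA relative to the spike-in in RDY73. The ratio of labelled S. cerevisiae to labelled S. pombe reads was 18.8 ± 1.96 with DMSO and 8.89 ± 0.813 with IAA (SD, n = 3), a log2 change of −1.08, or 2.11-fold, with no overlap between the groups (exact permutation p = 0.1, the smallest possible). In RDY234 the ratio was 36.3 ± 1.17 with DMSO and 33.7 ± 1.74 with IAA, a log2 change of −0.11 (exact permutation p = 0.2). The IAA effect differed between the strains by −0.97 log2 units (permutation of residuals, p = 0.005, the smallest possible). Libraries without 4tU gave a ratio of 0.865 ± 0.00462 in RDY73 and 1.95 ± 0.0904 in RDY234. The ratio of total reads changed by −0.29 in RDY73 (exact permutation p = 0.1) and −0.04 in RDY234 (exact permutation p = 0.8). The effect on total reads differed between strains by −0.25 (permutation of residuals, p = 0.045).

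**Figure D1:**
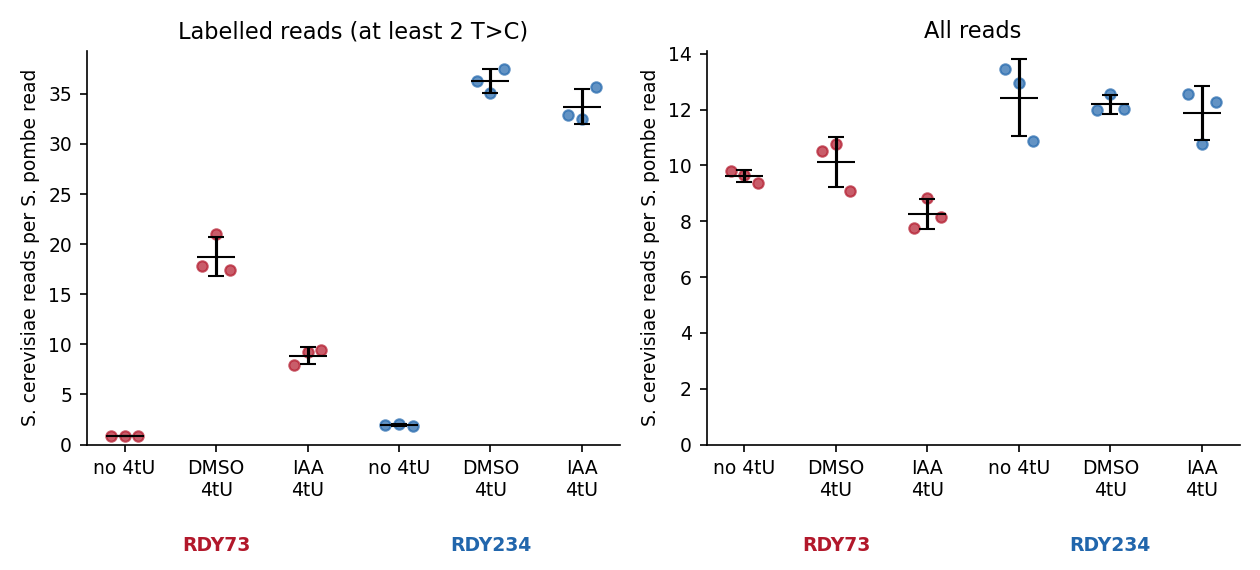
Ratio of S. cerevisiae to S. pombe reads per library, for labelled reads and for total reads, by strain and treatment; points are libraries and bars mark the mean and SD of 3. In RDY73 the lowest labelled ratio with DMSO was 17.5 and the highest with IAA was 9.48, and in RDY234 these were 35.1 and 35.7.

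The first gene-level comparison asks which genes lost new RNA when both tagged proteins were targeted. In RDY73, new RNA of 4359 of 5195 tested genes fell with IAA and that of 20 rose, with a median log2 change of −1.97 over all tested genes (3.91-fold lower, n = 3 libraries per group). 4023 genes fell by more than 2-fold. The median gene thus fell further than the summed labelled reads (2.11-fold), which abundant transcripts dominate. Large named falls were those of PRP6, a spliceosome component (YBR055C, chromosome II 344602 to 347301), at −5.18 ± 0.48 (SE, adjusted p = 4.17e-25), a 36.2-fold fall, and CHZ1, a histone chaperone for H2A.Z (YER030W, chromosome V 213437 to 213898), at −4.34 ± 0.50. OTU2 (−5.03 ± 0.55) and TMA16 (−3.87 ± 0.47) also fell far, and the windows of these last genes each overlap another on the same strand. LEO1, a subunit of the Paf1 elongation complex, fell by 3.50 ± 0.38. On this scale BDF1 new RNA fell by 0.65 ± 0.19 (adjusted p = 0.00127) and BDF2 by 0.36 ± 0.18 (adjusted p = 0.0496), but both turned positive without the spike-in (1.01 and 1.30), and the BDF2 call was lost under nearly every alternative and without any 1 of the 6 RDY73 libraries.

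These changes are per S. pombe read. When the libraries were instead scaled by TMM over the S. cerevisiae genes, without the spike-in, the median of all genes moved from −1.97 to −0.34 and 804 genes were called higher against 663 lower. Directions of gene groups below are therefore given under both scalings, and the second is called relative scaling.

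Genes for making ribosomes and the transcription machinery fell as groups. All 74 ribosome biogenesis genes fell (median −1.96), among them NOP8 at −3.46 ± 0.30, UTP8 at −2.83 ± 0.24 and RLP7 at −1.81 ± 0.15, and under relative scaling 15 fell and 3 rose. All 67 mitochondrial ribosomal protein genes fell (median −2.39), such as MRPL32 at −2.55 ± 0.20 and MRPL22 at −2.08 ± 0.21, and under relative scaling 22 fell and 1 rose. All 61 tested genes of RNA polymerase II, TFIID, SAGA and Mediator fell (median −2.30), such as TAF11 at −1.87 ± 0.19 and RPB4 at −2.09 ± 0.25, and under relative scaling 8 fell and 1 rose. These lists lay below the other genes in camera (adjusted p = 2.7e-07, 6.0e-06 and 0.0032). On the spike-in scale none of the calls held with an estimated correlation (adjusted p = 0.12, 0.097 and 0.21 with an estimated correlation). Under relative scaling ribosome biogenesis no longer passed (camera adjusted p = 0.15, adjusted p = 0.459 with an estimated correlation), while the mitochondrial ribosomal proteins (adjusted p = 0.00702 with an estimated correlation) and the transcription machinery (adjusted p = 0.0277 with an estimated correlation) did. The ribosome biogenesis median also lay close to the all-gene median, though below that of random lists matched on mean count (−1.57, percentile 0.05). Of 32 proteasome genes, 31 fell (median −1.81), such as PRE5 at −2.60 ± 0.26 and RPT3 at −2.03 ± 0.25, and under relative scaling 2 fell and 2 rose. The camera adjusted p for the proteasome was 0.018 (adjusted p = 0.26 with an estimated correlation), downward although the list median lay above that of all genes.

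Cytosolic ribosomal protein genes fell less far. Of 137 genes, 136 fell and 1 did not pass (median −1.23), with RPL33A at −1.78 ± 0.16 and RPS28A at −1.54 ± 0.15. Under relative scaling 84 of the 137 rose and none fell, and RPS28A was at 0.12. Camera placed the list below the other genes (adjusted p = 0.011, adjusted p = 0.61 with an estimated correlation), although its median lay above the all-gene median. The direction turned upward under relative scaling (adjusted p = 2.67e-16, adjusted p = 0.0291 with an estimated correlation) and with a threshold of 1 conversion (median −0.62, adjusted p = 0.00492, adjusted p = 0.683 with an estimated correlation). Random lists of the same size matched on mean count had a median of −1.10, and the list median lay at percentile 0.065 among 10000 of them. All 29 translation factor genes fell (median −1.54, camera adjusted p = 0.17), and under relative scaling 9 rose.

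Glycolytic and general stress genes were the main exception to the fall within RDY73. Among 18 glycolysis and fermentation genes, 5 rose, 2 fell and 11 did not pass (4 rose and 0 fell adjusted over the list alone), with a median of 0.03. ENO1, an enolase (chromosome VII 1000930 to 1002240), rose by 1.04 ± 0.20 (adjusted p = 8.24e-07) and TDH2, a glyceraldehyde-phosphate dehydrogenase (chromosome X 453683 to 454681), by 0.77 ± 0.15 (adjusted p = 6.27e-07). Under relative scaling all 18 rose. Among 21 stress genes under Msn2 and Msn4, 3 rose, 3 fell and 15 did not pass (3 rose and 1 fell adjusted over the list alone, median −0.03), with HOR7 at 0.22 ± 0.15 (adjusted p = 0.163) and SOD2 at −0.40 ± 0.22 (adjusted p = 0.0769). Under relative scaling 14 rose and 0 fell, with HOR7 at 1.89 and SOD2 at 1.25. These calls depended on single libraries and on the spike-in scaling: SOD2 fell by 0.62 (adjusted p = 0.0118) without DMSO replicate A and by 0.59 (adjusted p = 0.0195) without IAA replicate C, and HOR7 rose by 0.34 (adjusted p = 0.046) without DMSO replicate B and by 0.41 (adjusted p = 0.0104) with TMM over S. pombe genes. Both lists lay above the other genes in camera, with adjusted p = 1.2e-26 and 2.5e-19, and both calls held with an estimated correlation (adjusted p = 0.044 and 0.027), though not with a threshold of 1 conversion (adjusted p = 0.118 and 0.0764 with an estimated correlation). Of 23 Hsf1 chaperone genes 18 fell (median −0.63), among them HSP10 at −1.04 ± 0.18 and MBF1 at −0.83 ± 0.16, while under relative scaling 18 rose, HSP10 and MBF1 included. This list also lay above the other genes (camera adjusted p = 0.0032, adjusted p = 0.24 with an estimated correlation, and 0.00702 under relative scaling).

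Single genes rose outside these lists. NRD1, the RNA-binding subunit of the complex that ends short noncoding transcripts (YNL251C, chromosome XIV 172588 to 174315), rose by 1.11 ± 0.25 (adjusted p = 3.05e-05). SER3, the first enzyme of serine synthesis (YER081W, chromosome V 322686 to 324095), rose by 1.03 ± 0.22 (adjusted p = 5.23e-06), and its window overlaps another on the same strand. Fitted on the 6 compared libraries alone, 2739 of 3224 tested genes were called, because fewer genes passed the filter on low counts.

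**Figure D2:**
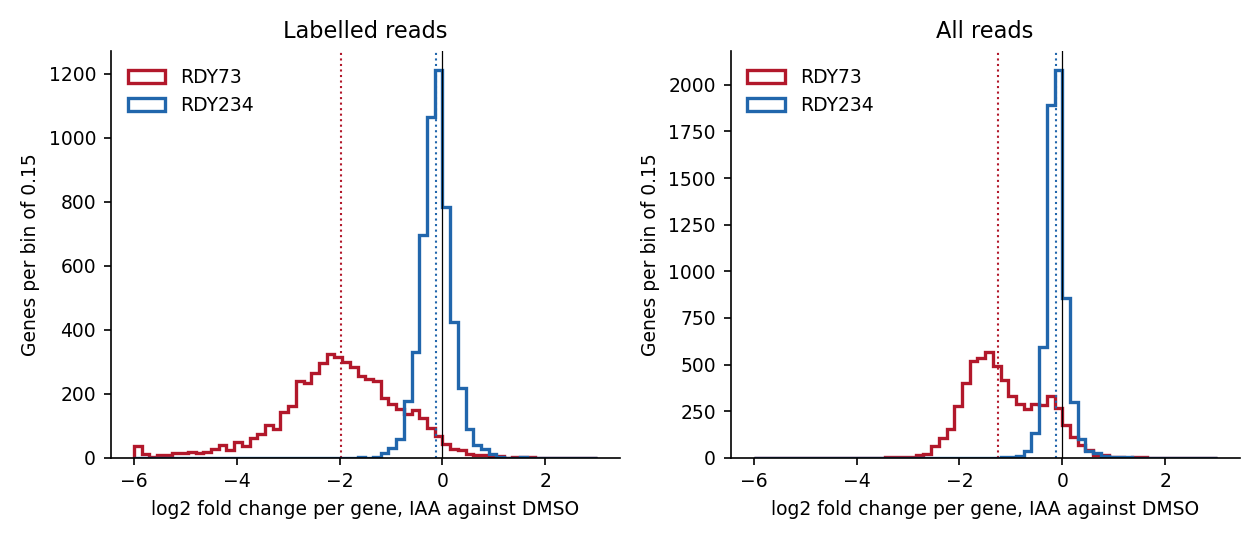
Histograms of log2 fold changes with IAA against DMSO over all tested genes, for labelled reads and total reads in each strain (horizontal axis, log2 fold change, with values below −6 in the first bin, and vertical axis, number of genes). The medians were −1.97 and −1.24 in RDY73 and −0.12 and −0.13 in RDY234, all scaled to the S. pombe reads.

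The same comparison in RDY234 asks what IAA did when an untagged Bdf1 was present. New RNA of 2 of 5195 genes passed the threshold. PDR12, a membrane pump that exports weak organic acids (YPL058C, chromosome XVI 445842 to 450377), rose by 1.56 ± 0.25 (adjusted p = 3.72e-06), from 39.1 ± 11.6 to 114 ± 12.9 scaled labelled reads (SD, n = 3). TIS11, an RNA-binding protein of the response to low iron (YLR136C, chromosome XII 415801 to 416658), fell by 1.10 ± 0.24 (adjusted p = 0.0139). The TIS11 call was lost under several alternatives. Its change was −0.42 without DMSO replicate B and −0.53 with a threshold of 1 conversion, while it was −1.03 with the replicate block, −1.07 in DESeq2, −1.09 without IAA replicate A and −1.03 without IAA replicate B. The all-gene median was −0.12, 245 genes had an unadjusted p under 0.05 and DESeq2 called 1 gene. BDF1 changed by −0.05 ± 0.15 (adjusted p = 0.993) and BDF2 by −0.35 ± 0.16 (adjusted p = 0.977).

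As a group, ribosome biogenesis genes lay below the other genes in RDY234 (median −0.29, camera adjusted p = 1.3e-06), with 0 of 74 past the threshold in edgeR, 245 genes at an unadjusted p under 0.05 over the whole set, and 1 gene in DESeq2. That list call was lost with an estimated correlation (adjusted p = 0.56 with an estimated correlation, and 0.105 under relative scaling, where the median was −0.15). Msn2 and Msn4 stress genes lay above the other genes (median 0.36, camera adjusted p = 9.4e-09, adjusted p = 0.25 with an estimated correlation, and 0.0266 under relative scaling), and 3 of 21 rose when adjusted over the list alone.

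The interaction asks whether the strains responded differently. New RNA of 3866 genes changed differently, 3854 of them lower in RDY73 relative to RDY234 and 12 higher, with a median difference of −1.82. PRP6 (−4.93 ± 0.56) and CHZ1 (−4.66 ± 0.57) had the most negative named differences. SER3 (1.21 ± 0.30, adjusted p = 0.000221), NRD1 (1.12 ± 0.36, adjusted p = 0.0034) and TDH2 (0.87 ± 0.21, adjusted p = 0.000101) had positive ones. ENO1 had 0.64 ± 0.30 (adjusted p = 0.0431), a call that was lost without any of 8 single libraries, with the replicate block (adjusted p = 0.0539), with no filter (adjusted p = 0.0518) and with background subtracted (adjusted p = 0.0543). For PDR12 the difference was −2.22 ± 0.41 (adjusted p = 7.54e-07), because it rose in RDY234 while its labelled reads in RDY73 went from 28.5 ± 3.36 to 18.3 ± 3.20 (log2 change −0.66, adjusted p = 0.0497, and 0.98 under relative scaling). That fall of PDR12 in RDY73 was lost under nearly every alternative, among them the replicate block (adjusted p = 0.0582), DESeq2 (adjusted p = 0.0515), no filter (adjusted p = 0.0589) and leaving out DMSO replicate A or C or IAA replicate B or C (adjusted p = 0.0656, 0.153, 0.149 and 0.071). Under relative scaling the PDR12 difference was −0.71 (adjusted p = 0.204). By list, 135 of 137 cytosolic ribosomal protein genes, 70 of 74 ribosome biogenesis genes, 66 of 67 mitochondrial ribosomal protein genes and 31 of 32 proteasome genes were lower in RDY73. Under relative scaling the ribosomal protein genes flipped, with 42 higher and 0 lower, and 7, 15 and 2 genes of the other lists were lower. Of the 24 lists, 17 passed camera with the preset correlation and 0 with an estimated one on the spike-in scale (smallest adjusted p = 0.0766 with an estimated correlation). Under relative scaling 18 and 14 passed. On the spike-in scale the glycolysis list had a median difference of 0.04 and the Msn2/4 stress list one of −0.46. Stress genes, with a median of −0.03 in RDY73 itself, were thus lower there relative to RDY234, though by less than most genes.

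**Figure D3:**
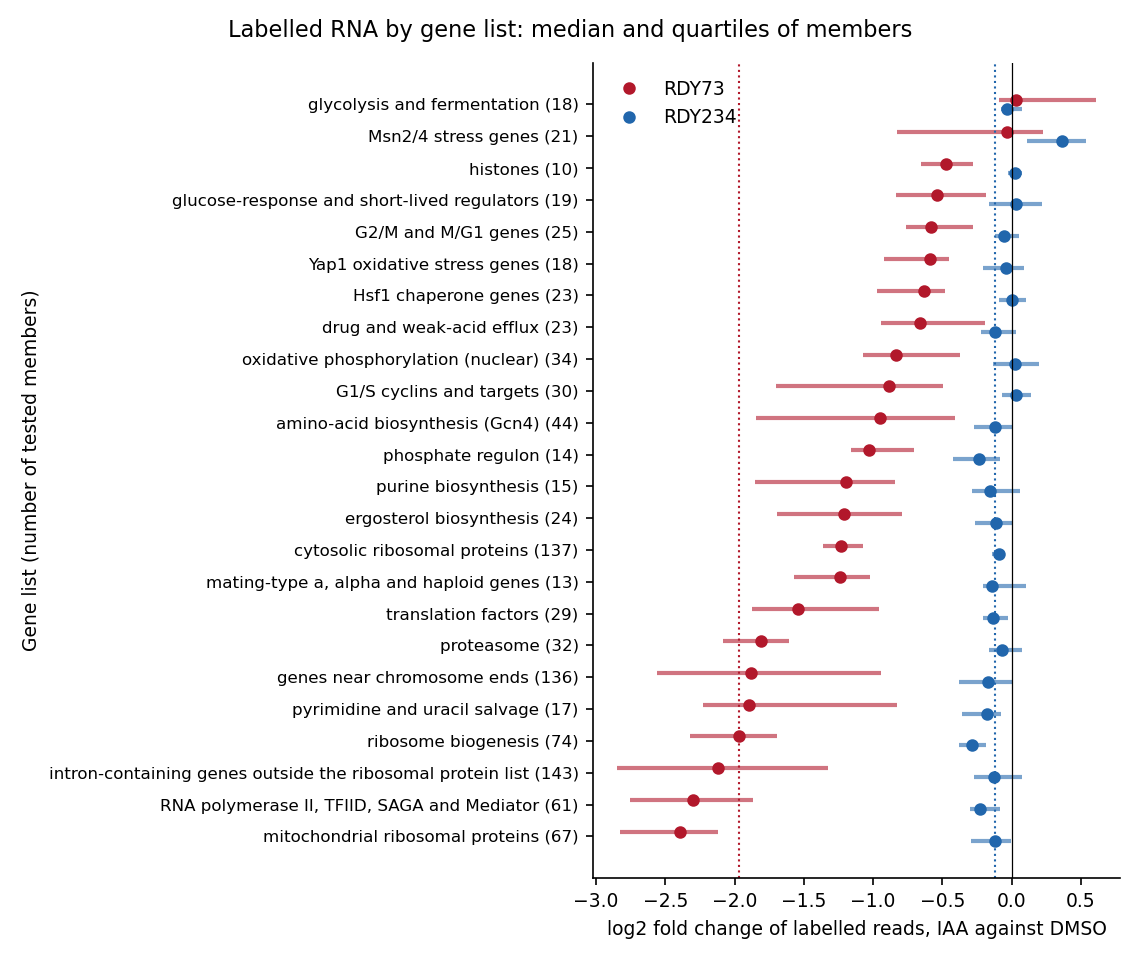
Log2 fold change of labelled reads, IAA against DMSO, by gene list in RDY73 and RDY234: points are list medians, bars the quartiles of the members, and dotted lines the medians of all tested genes (−1.97 and −0.12). Glycolysis (0.03) and Msn2/4 stress genes (−0.03) lay highest in RDY73 and mitochondrial ribosomal proteins (−2.39) lowest, on the spike-in scale. Without the spike-in all medians in RDY73 move up and that of the cytosolic ribosomal proteins, for example, becomes 0.44.

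Total RNA fell in RDY73 as well, by less. Of 6100 genes 4752 fell and 71 rose, with a median of −1.24 (2.37-fold lower, n = 3 per group), and 3686 fell by more than 2-fold. FAL1, a helicase of ribosome assembly (−2.92 ± 0.28), NOP19 (−2.79 ± 0.22) and CSE2, a Mediator subunit (YNR010W, chromosome XIV 643744 to 644193, −2.78 ± 0.25), were among the largest falls. NRD1 rose by 1.58 ± 0.13 (adjusted p = 5.62e-14) and HRP1, a subunit of the cleavage factor that processes mRNA 3′ ends (YOL123W, chromosome XV 87844 to 89448), by 1.05 ± 0.13 (adjusted p = 2.14e-09). GAS2, a cell wall glucanosyltransferase, rose by 1.65 ± 0.25 in a window that overlaps another on its strand, ARG3 of arginine synthesis by 1.06 ± 0.24, and SER3 by 0.90 ± 0.15. Under relative scaling the median was −0.12, and 1778 genes were called higher against 1934 lower.

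The groups again fell by different amounts in total RNA. All 74 ribosome biogenesis genes fell (median −1.54, NOP8 at −2.59 ± 0.16), all 67 mitochondrial ribosomal protein genes fell (median −1.67, MRPL33 at −2.21 ± 0.15), and 62 of 63 transcription machinery genes fell (median −1.45, MED11 at −2.25 ± 0.18 and TAF13 at −2.13 ± 0.17). Under relative scaling 49 fell and 8 rose, 48 fell and 2 rose, and 29 fell and 6 rose in these lists. Of 32 proteasome genes 31 fell, and RPN4, the activator of proteasome genes, named after its value was seen, rose by 0.53, while under relative scaling 14 fell and 3 rose. Of 137 cytosolic ribosomal protein genes 64 fell (50 adjusted over the list alone), with a median of −0.25 against −0.24 for random lists matched on mean count (percentile 13.5), led by RPL15B (−1.68 ± 0.16) and RPL22B (−1.37 ± 0.14, with an overlapping window), and under relative scaling 135 rose. Of 30 Msn2/4 stress genes 10 rose and 2 fell (8 and 2 adjusted over the list alone), among them the catalase gene CTT1 at 0.77 ± 0.17, and of 19 glycolysis genes 5 rose and 1 fell, among them TDH2 at 0.65 ± 0.12 and ENO1 at 0.61 ± 0.14. Under relative scaling 29 and 18 of these rose. BTN2, an Hsf1 target, rose by 0.77, and SRX1, a Yap1 target that reduces oxidized peroxiredoxins, by 0.92. The medians of the Hsf1 and Yap1 lists lay below 0, at −0.11 and −0.16, so these genes do not stand for their lists. Of 26 lists, 19 passed camera with the preset correlation and 0 with an estimated one on the spike-in scale (smallest adjusted p = 0.129 with an estimated correlation), and under relative scaling 21 and 16 passed.

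In RDY234 total RNA of 2 of 6100 genes passed. PDR12 rose by 2.01 ± 0.16 (adjusted p = 4.38e-13), from 216 ± 36.8 to 875 ± 42.8 scaled reads, and PHO12, an acid phosphatase of the phosphate response (YHR215W, chromosome VIII 552099 to 553502), fell by 0.73 ± 0.14 (adjusted p = 0.0201). The PHO12 call was lost without DMSO replicate B, DMSO replicate C, IAA replicate A or IAA replicate B. PDR12 total RNA rose in RDY73 too, by 0.66 (from 160 ± 14.3 to 251 ± 57.5 scaled reads, adjusted p = 0.000292). The median over all genes was −0.13, 482 genes had an unadjusted p under 0.05, and DESeq2 called 2 genes. Ribosome biogenesis genes lay below the other genes (median −0.27, camera adjusted p = 2.3e-13, adjusted p = 0.84 with an estimated correlation) and Msn2/4 stress genes above them (median 0.16, camera adjusted p = 7.4e-16, adjusted p = 0.82 with an estimated correlation). Under relative scaling these were adjusted p = 0.143 and 0.0476 with an estimated correlation.

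Total RNA of 4264 genes changed differently in the 2 strains, 4231 lower in RDY73 relative to RDY234 and 33 higher, with a median difference of −1.10. CSE2 had −2.82 ± 0.32, NRD1 1.46 ± 0.19, HRP1 1.12 ± 0.19 and PDR12 −1.35 ± 0.22 (adjusted p = 1.15e-06). Under relative scaling the PDR12 difference was −0.35 (adjusted p = 0.105), and 1378 genes were higher against 1331 lower. Of 137 cytosolic ribosomal protein genes 23 were lower, and under relative scaling 133 were higher. All 67 mitochondrial ribosomal protein genes and 72 of 74 ribosome biogenesis genes were lower, against 38 and 25 under relative scaling.

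New and total RNA changes were compared across the 5195 genes tested for both. In RDY73 Pearson's r was 0.72 and Spearman's rho 0.74, 4052 genes fell in both, 15 rose in both, and 3 went opposite ways. In RDY234 r was 0.54 and rho 0.51. Both kinds of count come from the same libraries, and genes are not independent replicates, so these values describe the libraries and carry no p.

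The strains differed before IAA. With DMSO and 4tU, the labelled ratio was lower in RDY73 by 0.96 log2 units (1.94-fold, exact permutation p = 0.1, the smallest possible), the labelled share by 0.84 and the total ratio by 0.27. New RNA of 4131 genes was lower in RDY73 than in RDY234 and that of 16 was higher (median −1.13), and under relative scaling the median was −0.02, with 271 genes higher and 168 lower. BDF1 had −2.26 ± 0.17 (adjusted p = 7.56e-36). LEU1 (−2.20 ± 0.21) and BAT1 (−2.19 ± 0.23), of leucine synthesis, and DBP3 (−1.89 ± 0.16) and RLP7 (−1.81 ± 0.14), of ribosome assembly, were lower. YGP1, a stress-induced secreted glycoprotein, was higher at 1.62 ± 0.27 (adjusted p = 2.06e-08). All 74 ribosome biogenesis genes were lower (median −1.23, camera adjusted p = 1.9e-07, adjusted p = 0.44 with an estimated correlation), and under relative scaling 12 were.

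In total RNA, 4339 genes were lower in RDY73 and 159 higher (median −0.64), against 708 lower and 941 higher under relative scaling. Stress genes stood out among the higher ones. Of 30 Msn2/4 genes 20 were higher and 0 lower (median 0.58, camera adjusted p = 2.5e-42, adjusted p = 0.045 with an estimated correlation), and under relative scaling 26 were. DDR2 (2.20 ± 0.15), YGP1 (1.79 ± 0.14) and HSP12 (1.72 ± 0.15) led the list. HXT7, a high-affinity glucose transporter, was higher by 1.40 ± 0.16. LEU1 (−1.59 ± 0.14), BAT1 (−1.47 ± 0.14) and FUS1, a mating gene (−1.97 ± 0.23), were lower. BDF2 was lower at −0.46 ± 0.13 (adjusted p = 0.00202) but at 0.16 under relative scaling, while TRP1 was lower at −4.54 ± 0.22. All 74 ribosome biogenesis genes were lower (median −0.92), against 42 under relative scaling. Cytosolic ribosomal protein genes were mixed, with 45 lower and 2 higher (median −0.08), and 100 were higher under relative scaling. The labels give no batch, so strain and any day of culture or library preparation cannot be told apart. The S. pombe reads themselves differed between the strains' libraries. Of these reads 13.5% to 20.2% were multimapped in RDY234 libraries and 6.95% to 9.19% in RDY73 libraries. S. pombe conversions per covered T were 0.516% to 0.641% and 0.379% to 0.441%. Differences between strains per S. pombe read therefore rest on spike-in reads that were not alike, and the cause was not tested.

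4tU itself changed few genes, and some of them changed in both strains. In RDY73 31 genes rose and 9 fell with 4tU and DMSO against no 4tU, and in RDY234 24 rose and 11 fell, of 6100 tested. YLR460C, of the quinone oxidoreductase family (chromosome XII 1059760 to 1060890), rose by 3.87 ± 0.24 in RDY73 and 3.67 ± 0.22 in RDY234 (SE, n = 3 per group). FLR1, a drug exporter (YBR008C, chromosome II 252563 to 254209), rose by 2.88 ± 0.15 and 1.94 ± 0.15, OYE2, an NADPH oxidoreductase, by 1.96 ± 0.13 and 1.48 ± 0.12, ATR1, another exporter, by 1.65 ± 0.19 and 1.52 ± 0.18, and SRX1 by 1.08 and 0.97. GRE2, a reductase induced by stress, rose by 1.63 ± 0.12 and 1.85 ± 0.12 in a window that overlaps another. CIP1 (−1.16 ± 0.21 and −0.97 ± 0.22), the kinase gene TDA1 (−0.91 ± 0.14 and −0.87 ± 0.13) and RPI1 (−0.97 ± 0.15 and −0.71 ± 0.14) fell in both, although the CIP1 call in RDY234 was lost without control replicate C (adjusted p = 0.0515), DMSO replicate B (adjusted p = 0.144) or DMSO replicate C (adjusted p = 0.0742). The SRX1 call was lost in RDY73 without control replicate C (adjusted p = 0.062), and in RDY234 without control replicate C (adjusted p = 0.141) or DMSO replicate B (adjusted p = 0.274) and with the compared libraries alone (adjusted p = 0.0772). 19 genes rose in both strains, where independent lists of these sizes would share 0.122, and 3 fell in both, where they would share 0.0162. The strains share no libraries.

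By list, Yap1 oxidative stress genes lay above the other genes with 4tU: 7 of 19 rose and 1 fell in RDY73 (11 and 1 adjusted over the list alone, median 0.31, camera adjusted p = 1.35e-15), and 6 rose in RDY234 (8 adjusted over the list alone, median 0.15, camera adjusted p = 1.58e-15). On the spike-in scale neither call held with an estimated correlation (adjusted p = 0.13 with an estimated correlation in both), while under relative scaling both did (adjusted p = 4.2e-05 and 3.41e-05 with an estimated correlation). Ribosome biogenesis genes lay above the other genes (median 0.25 and 0.22, 1 of 74 past the threshold in each strain, and 11 and 15 adjusted over the list alone), with adjusted p = 0.79 and 0.54 with an estimated correlation (0.125 and 0.0521 under relative scaling). Msn2/4 stress genes lay below the other genes in both strains (median −0.13 and −0.23, camera adjusted p = 0.00146 and 1.93e-07), as did glucose-response regulators (median −0.18 and −0.22, camera adjusted p = 0.000198 and 1.33e-05) and, in RDY234, G1/S genes (median −0.09, camera adjusted p = 0.00341). None of these calls held with an estimated correlation on the spike-in scale, and under relative scaling those of the glucose-response regulators (adjusted p = 0.0203 with an estimated correlation) and G1/S genes (adjusted p = 0.0141 with an estimated correlation) held in RDY234 alone. Drug and weak-acid efflux genes did not pass (camera adjusted p = 0.0716 and 0.139). REI1, of the ribosome biogenesis list, rose by 0.58 ± 0.14 in RDY73 (adjusted p = 0.0298) and 0.63 ± 0.14 in RDY234 (adjusted p = 0.00886). Of the pyrimidine salvage genes FUR1, which converts uracil to its nucleotide, rose by 0.59 ± 0.13 in RDY73 (adjusted p = 0.0121), a call lost without control replicate A, control replicate C or DMSO replicate B. The REI1 call in RDY73 was lost without any 1 of its 6 libraries, and that in RDY234 without control replicate C (adjusted p = 0.0945), DMSO replicate A (adjusted p = 0.0729) or DMSO replicate B (adjusted p = 0.0995) and with the compared libraries alone (adjusted p = 0.0855). Calls near the threshold hung on single libraries: without RDY73 control replicate C 20 genes were called and without RDY73 DMSO replicate B 23, and without RDY234 DMSO replicate A 22 and DMSO replicate B 21. The balance in RDY234 moved too, with 16 risen and 20 fallen without control replicate C and 30 risen and 4 fallen without control replicate A. Relative scaling moved the counts to 66 and 103 genes.

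**Figure D4:**
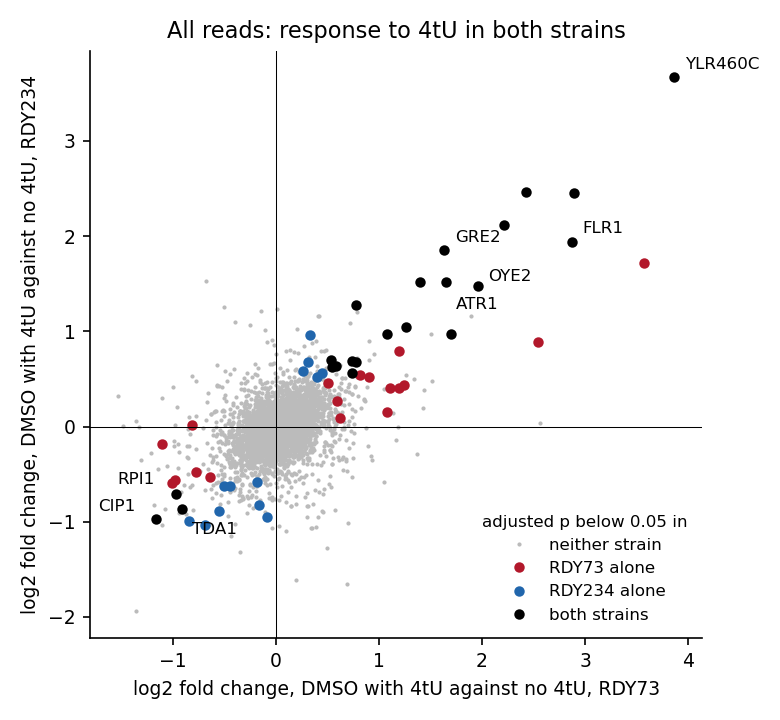
Log2 fold change of total reads with DMSO and 4tU against no 4tU in RDY73 (horizontal axis) and RDY234 (vertical axis); each point is a gene and colour shows in which strain its adjusted p passed the threshold. YLR460C lay farthest out at 3.87 and 3.67, and RPI1 and TDA1 fell in both strains.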

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

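The tests of spike-in mixing, of mitochondrial reads, of covered T, of conversions per labelled read and of attenuated genes, and both schemes of regrouping for the interactions, were chosen after the results they bear on were seen.

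The strains differed in their response to IAA. The IAA effect on the labelled ratio differed by −0.97 log2 units and that on the total ratio by −0.25, new RNA of 3866 genes responded differently, and total RNA of 4264 genes did. Each was singled out because a test of the difference between the strains passed its threshold.

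The first pattern weighed is the deeper fall of new RNA in RDY73. Unequal mixing of S. pombe cells would leave the labelled share of S. cerevisiae reads alone. Yet that share also fell further in RDY73, by −0.66 log2 units, so the tables argue against mixing as the whole cause. A part could still come from mixing, since the total ratio, which mixing would change, differed by −0.25. Without the multimapped S. pombe loci the difference in the labelled ratio was −0.97, so the tables argue against those loci as the cause. Weaker labelling of the RDY73 IAA libraries as the whole cause would lower mitochondrial transcripts, which another polymerase makes, as much as nuclear ones, but these changed by −0.44 against −1.13 for nuclear reads (164 to 257 mitochondrial labelled reads per library). The control libraries of RDY73 already held 74 to 101 labelled mitochondrial reads, so the mitochondrial change rests on few reads above background. A part of the fall could still come from weaker labelling. Among reads with at least 1 conversion, background subtracted, 53.2% had at least 2 in RDY73 with DMSO. With IAA 50.0% did, without overlap between the groups, which goes with weaker labelling. In RDY234 the shares were 64.5% and 64.1%. The untagged BDF1 copy is the difference the design names, it remains a hypothesis, and strain and batch cannot be told apart.

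The second pattern is the smaller amount of labelled RNA in RDY73 before IAA. Covered T per S. cerevisiae read differed by −0.019 log2 units, which does not account for it. With background subtracted the ratio still differed by −0.95, so background reads added to the labelled ones do not account for it either. Background was a small part of the labelled reads, so subtraction could move the ratio little. It does not test a proportional difference in conversions between the strains' libraries. S. pombe reads covered more T in RDY73 (30.4 against 26.7 per read), yet a smaller share of them was labelled (2.20% against 2.45%). A smaller labelled S. pombe share raises the ratio, so it does not account for the lower ratio in RDY73. The labelled share of S. cerevisiae reads, which uses no S. pombe reads, also differed by −0.84. Among reads with at least 1 conversion, background subtracted, 53.2% had at least 2 in RDY73 and 64.5% in RDY234, a difference of −11.3 percentage points. Labelled mitochondrial reads, background subtracted, also differed by −0.87 log2 units, against −0.95 for nuclear reads, with no overlap between the strains (164 to 427 mitochondrial labelled reads per library). Libraries without 4tU already held 74 to 101 such reads in RDY73 and 182 to 228 in RDY234, so the mitochondrial difference rests on few reads above background. Both values go with lower incorporation of 4tU in RDY73, which may account for the difference in part or in whole. However, libraries without 4tU differed in the same direction: 0.202% of S. cerevisiae reads were labelled in RDY73 and 0.373% in RDY234. Conversions per covered T in S. pombe reads were also lower in RDY73 libraries. Lower incorporation therefore cannot be told apart from a difference between the strains' libraries in conversions of any origin. However, libraries without 4tU differed in the same direction: 0.202% of S. cerevisiae reads were labelled in RDY73 and 0.373% in RDY234. Conversions per covered T in S. pombe reads were also lower in RDY73 libraries. Lower incorporation therefore cannot be told apart from a difference between the strains' libraries in conversions of any origin. Less synthesis by both polymerases would lower mitochondrial reads too and was not tested. Strain and batch cannot be told apart here either.

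The third pattern is the set of 71 genes whose total RNA rose in RDY73 against the general fall. Reads from an overlapping window on the same strand are argued against as the cause, since 14.1% of these genes had one against 20.2% of the others (Fisher's exact p = 0.235). NRD1 and HRP1 encode RNA 3′-end factors, so release from early termination was tested on 8 genes known for attenuation: 0 rose and 4 fell (PCF11, ADE12, GSC2 and URA2), with a median of −0.31. That median lay at percentile 97.7 of random lists, and at 96.4 with the 7 genes matched at first, before the last symbol was matched with that result in view. With so few genes on either side of the limit, attenuation cannot be told apart from a chance choice of genes. No other biological explanation was tested.

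Regroupings of the libraries were counted for each comparison of genes. For the interaction in new RNA, 2 of 100 regroupings, the real one included, gave as many genes (3866, highest other 4240), and for total RNA 5 of 100 did (4264, highest other 4974). Neither count settles whether chance can be excluded, because the scheme was chosen with results in view. It also moves whole libraries between groups, so strain and IAA differences enter the contrast. The counts therefore do not show what to expect without an interaction, and they speak neither for nor against chance. A first scheme, which swapped strain labels within each treatment in 20 draws, had given 4 of 20 for both (highest other 4860 and 5119). That was before the later scheme and its number of draws were set. Swapped strain labels likewise let the strain difference enter the contrast. The cause of the large counts in other regroupings was not tested.

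For comparisons of 3 libraries with 3, the 10 splits are too few for a share under 0.05. New RNA in RDY73 gave 4379 genes (highest other split 0) and in RDY234 2 (highest other 1), and the strains 4147 (highest other 0). Total RNA in RDY73 gave 4823 (highest other 0), in RDY234 2 (highest other 6), and the strains 4498 (highest other 0). The response to 4tU gave 40 genes in RDY73 (highest other 0) and 35 in RDY234 (highest other 22). The counts of 0 are from edgeR.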

How the results depend on the processing

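Leaving out multimapped S. pombe loci, subtracting background, leaving out overlapping windows, using protein-coding genes alone for the ratio, and joining an estimated correlation with another scaling or threshold were alternatives chosen after seeing the data. The difference between strains in the labelled ratio ran from −1.02 to −0.61 over 17 alternatives, with p = 0.005 by permutation of residuals in each.

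Scaling without the spike-in moved most counts, because it sets the general change near 0 by construction. With TMM over S. cerevisiae genes and with DESeq2 size factors, new RNA gave 1467 genes (804 higher, 663 lower) and 1443 (853 higher, 590 lower) in RDY73, 4 and 7 in RDY234, 950 (566 higher, 384 lower) and 961 (602 higher, 359 lower) in the interaction, and 439 (271 higher, 168 lower) and 456 (304 higher, 152 lower) between strains. Total RNA gave 3712 (1778 higher, 1934 lower) and 3477 (1967 higher, 1510 lower) in RDY73, 17 and 17 in RDY234, 2709 (1378 higher, 1331 lower) and 2506 (1553 higher, 953 lower) in the interaction, and 1649 (941 higher, 708 lower) and 1632 (972 higher, 660 lower) between strains. The response to 4tU gave 66 and 66 genes in RDY73 (44 higher, 22 lower in each) and 103 (74 higher, 29 lower) and 102 (73 higher, 29 lower) in RDY234. The all-gene median for new RNA in RDY73 was −0.34 and −0.28, and −1.80 with TMM over S. pombe genes. In RDY73 new RNA these 2 scalings reversed BDF1 (1.01 and 1.06), BDF2 (1.30 and 1.35), RPS28A (0.12 and 0.17), HSP10 (0.62 and 0.67), MBF1 (0.84 and 0.90), PDR12 (0.98 and 1.04) and SOD2 (1.25 and 1.30), in total RNA of RDY73 BDF1 (1.06 and 1.16) and BDF2 (0.94 and 1.04), and in total RNA between strains BDF2 (0.16 and 0.17). SOD2 and the total RNA of BDF1 and BDF2 in RDY73 were not called on the spike-in scale. RPL33A, RLP7, MRPL22, TAF11, RPB4 and RPT3 lost their calls in both. With TMM, new RNA in RDY234 gave 9 lists in place of 5.

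With at least 1 conversion, new RNA in RDY234 gave 1 gene, and BDF2 (0.094) and PDR12 (0.018) turned positive in RDY73. The cause was not tested. New against total changes then gave Pearson's r 0.861 and Spearman's rho 0.875 in RDY73 and 0.672 and 0.658 in RDY234, and over the 614 genes with a mean of at least 100 reads 0.891 and 0.872, and 0.712 and 0.698.

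Fitted on the compared libraries alone, new RNA gave 2739 genes in RDY73, where 3224 were tested, and 4 in RDY234, and 4tU gave 84 genes (58 higher, 26 lower) in RDY73 and 23 (16 higher, 7 lower) in RDY234. DESeq2 gave 1 gene for new RNA in RDY234, and scaling without multimapped loci 4. The cause was not tested. With an estimated correlation on the spike-in scale, lists past the threshold numbered 4 (RDY73), 0 (RDY234), 0 (interaction) and 1 (strains) in new RNA, and 0, 0, 0 and 1 in total RNA, with 0 for 4tU in both strains. With TMM over S. cerevisiae genes and an estimated correlation they numbered 16, 2, 14 and 10, then 16, 4, 15 and 5, and 1 (RDY73) and 3 (RDY234) for 4tU. With at least 1 conversion and an estimated correlation new RNA gave 0, 0, 0 and 1.

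Replicate letters did not pair the samples: the 18 correlations between libraries of the same letter ran from −0.10 to 0.14. With the replicate block, new RNA in RDY234 gave 1 gene, other counts of genes stayed within 1.5 times, and the p of the labelled ratio in RDY73 was 0.25, the smallest that 3 pairs allow.

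With each library left out in turn, new RNA in RDY234 gave 1 to 4 genes (1 without DMSO B, IAA A or IAA B, 4 without DMSO C) and total RNA 1 to 5 (1 without DMSO B, DMSO C or IAA A, 5 without IAA B). 4tU gave 20 to 30 genes in RDY73 (20 without control C, 23 without DMSO B) and 21 to 36 in RDY234 (21 without DMSO B, 22 without DMSO A). Over all other alternatives, values of named genes for new RNA in RDY73 kept direction and call 274 times, lost the call 27 times, gained it 3 times and reversed 16 times, and for total RNA in RDY73 199 kept both, 1 lost the call and 4 reversed. In simulated counts for new RNA in RDY73, 55% of 2-fold falls of better-covered genes were found.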

Other observations

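The tests of a TATA box and of turnover were written before their results were seen. Several other gene groups fell less than most genes in new RNA of RDY73. Of 25 G2/M and M/G1 genes 11 fell and 0 rose in edgeR (6 fell adjusted over the list alone, median −0.58), and of 19 glucose-response regulators 8 fell and 1 rose (6 and 0 adjusted over the list alone, median −0.54), while without the spike-in 20 and 12 of them rose and 0 fell. Both lay above the other genes in camera (adjusted p = 2.02e-06 and 2.71e-07), also with an estimated correlation (adjusted p = 0.0448 and 0.044 with an estimated correlation), but not with a threshold of 1 conversion (adjusted p = 0.212 and 0.146 with an estimated correlation). On the spike-in scale other lists lay above the other genes with the preset correlation alone: drug and weak-acid efflux (13 of 23 fell, median −0.66, adjusted p = 0.0709 with an estimated correlation), Gcn4 amino-acid genes (30 of 44 fell and 1 rose, −0.95, adjusted p = 0.173 with an estimated correlation), oxidative phosphorylation (19 of 34 fell, −0.83, adjusted p = 0.228 with an estimated correlation), Yap1 genes (12 of 18 fell and 1 rose, −0.59, adjusted p = 0.218 with an estimated correlation), histones (7 of 10 fell, −0.47, adjusted p = 0.31 with an estimated correlation), G1/S genes (20 of 30 fell, −0.89, adjusted p = 0.218 with an estimated correlation) and genes near chromosome ends (100 of 136 fell, −1.88, adjusted p = 0.0974 with an estimated correlation). Without the spike-in 17, 19, 24, 15, 9, 14 and 25 members of these rose, against 0, 1, 0, 0, 0, 2 and 10 that fell. Without the spike-in the first 6 passed with an estimated correlation too (adjusted p = 0.00702, 0.0169, 0.00628, 0.00831, 0.0307 and 0.00593 with an estimated correlation), and the chromosome ends did not pass (adjusted p = 0.487). Lists that did not pass on the spike-in scale were the phosphate regulon (11 of 14 fell, −1.03), ergosterol (20 of 24, −1.21), pyrimidine (14 of 17, −1.90) and purine synthesis (12 of 15, −1.20), mating genes (10 of 13, −1.24) and intron-containing genes (129 of 143, −2.12), and without the spike-in their medians were 0.59, 0.45, −0.26, 0.44, 0.42 and −0.48, with adjusted p = 0.00131, 0.00132, 0.481, 0.0283, 0.00923 and 0.333 (0.156, 0.0494, 0.459, 0.255, 0.0629 and 0.343 with an estimated correlation).

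In total RNA of RDY73 the 5 engineered loci had a median of −0.25 with 0 past the threshold in edgeR (0.88 without the spike-in), and of 15 meiosis genes 6 fell (4 adjusted over the list alone, median −1.03, and 0.06 without the spike-in). Camera placed the meiosis list above the other genes (adjusted p = 0.00944, adjusted p = 0.4 with an estimated correlation). Between strains before IAA, 36 of 45 Gcn4 amino-acid genes and 13 of 19 mating genes had less total RNA in RDY73 and 1 of each had more, and without the spike-in 9 and 7 were lower and 8 and 2 higher.

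A first hypothesis was that genes with a TATA box lost less new RNA. Of 5025 genes searched 200 to 50 bp upstream, 892 had one, and their median change in RDY73 was −1.40 against −2.08 for the rest, at percentile 100 of random lists matched on mean count. Without the glycolysis, Msn2/4 and ribosomal protein lists 855 genes gave −1.45, also at percentile 100. A weaker dependence of TATA genes on Bdf1 and Bdf2 is a candidate explanation for this, and binding was not measured.

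A second hypothesis was that total RNA fell more where turnover was faster. Across 4240 genes, the labelled share in RDY234 with DMSO and the total RNA change in RDY73 had a Spearman correlation of −0.36 (Pearson −0.27). Genes are not independent replicates. Given mean total count the correlation was −0.11, so much of it may go with abundance. In 4 equal groups of genes from the lowest to the highest labelled share, median total changes were −0.68, −1.33, −1.51 and −1.44, and those of new RNA went in similar steps (−1.46, −2.02, −2.12 and −2.06). Given the new RNA change the correlation was −0.35.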
